A study of Mus musculus with 9 samples.

How the data were processed

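The series holds 9 single-cell RNA libraries from mouse lymph nodes: brachial, inguinal and mesenteric nodes at embryonic day 17.5 (E17.5), postnatal day 2 (P2) and postnatal day 60 (P60), with 1 library per node and age. Per the labels, each library is a pool of nodes from 30 embryos, 14 pups or 5 adults of the C57BL6/N strain, captured with 10x Genomics 3' chemistry and sequenced on an Illumina NextSeq. The pools of the 3 nodes and 3 ages are taken as separate pools, and whether the nodes of an age came from the same animals is not given in the sources used here. The tissue characteristic reads brachial for every E17.5 and P60 library while the sample titles name 3 nodes, so the node was taken from the title. Per the labels, the E17.5 cells were sorted as CD45-negative with high VCAM1 and ICAM1 after collagenase, dispase and DNase. The P2 cells were depleted of CD45-positive cells with beads after Liberase and came from Isl1Cre;R26YFP reporter pups, and the P60 cells were sorted as CD45-negative by CD31 and GP38 after collagenase, Liberase and DNase. Age is therefore inseparable from the sort, the enzymes and, for P2, the genotype, so a difference between ages is a difference between age and preparation together.

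The deposited count matrices hold unique molecular identifier (UMI) counts per gene and cell barcode, per the submitters' processing notes and the whole-number values in the files. Per the submitters' processing notes, the E17.5 and P60 libraries were counted with Cell Ranger 4.0.0. The notes for P2 name Cell Ranger 2.1.1, STAR 2.5.3a, Subread, featureCounts 1.6.2, SAMtools 1.4 and UMI-tools 0.5.4 and 0.5.5, on GRCm38, and which of these tools made the deposited counts is not given in the sources used here. The E17.5 and P60 tables list 32285 genes, and the P2 tables list only genes with a count, 33392 in at least 1 of the 3. The 22461 genes found in the first set and in at least 1 P2 table were used throughout, matched by symbol. Positions, gene types and overlaps were taken from GENCODE vM21 on GRCm38, which matched 22411 of these genes and 348 of the 349 named here; Sept2 was not matched. For each gene, exon bases overlapping another gene on either strand were counted, and the last 500 transcript bases were compared with all other genes in words of 60 bases at a step of 10. A gene named below with such an overlap, or with at least 50% of that stretch shared, is called uncertain, since its reads can be counted to another gene.

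Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Of its genes, mt-Co3, mt-Atp6 and mt-Co2 were read at 1, 3 and 1 UMIs over the P2 mesenchymal-like sums, so they add little to the percentage there. Of the deposited barcodes, 133, 161 and 97 (brachial, inguinal, mesenteric) had fewer genes at E17.5, 2468, 468 and 2193 at P2, and 667, 709 and 5298 at P60. Scrublet scores were computed in scanpy 1.11.5 for each library. The automatic thresholds marked 0.399%, 0.202% and 0.127% of cells at E17.5, 0.318%, 0.353% and 0.466% at P2, and 4.25%, 4.60% and 0.0353% at P60. After these shares were seen, the highest scores were taken out at an expected 0.8% per 1000 cells instead, which removed between 2.03% (brachial P2) and 8.20% (inguinal P60) of a library. Each age was then clustered alone: counts scaled per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours with shared-neighbour weights, and Leiden clustering at resolution 0.8 and random seed 1 (anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Figures were drawn with matplotlib 3.10.9.

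Clusters were named from 21 marker lists written before the files were opened. A marker counted as detected in a cluster at 20 CPM or more (counts scaled to the library or cluster total) and at 10% or more of its second-highest cluster. Fibroblastic clusters needed at least 4 detected fibroblast markers with Pdgfra among them, and endothelial clusters at least 4 detected endothelial markers, with a mean log2 gap of at least 0.5 between lymphatic and blood lists. Other classes needed 3 detected markers and a mean log2 ratio to all clusters of at least 1, and clusters with both fibroblast and endothelial markers were called mixed and left unnamed. A cluster was also left unnamed where its 10 leading genes held more markers of another class than of its own. The same was done where they held 0 of its own and its median UMIs lay under the library median divided by 3. Within the mesenchymal-like class, clusters with at least 4 detected lymphoid stroma markers are called lymphoid-stroma-like, and others with the CD34-positive fibroblast markers adventitial-like. Prior values were 5 CPM for the marker ratios and 20 CPM for the leading genes. These details of the naming rule were set after the clusters had been seen. A version that compared leading genes with cells of the other classes only was tried when a large mesenteric E17.5 cluster was seen to drop out, and the plain version was restored before any fold change was seen; both are among the alternatives. Class names are marker-based and carry "-like". Some clusters met the fibroblastic rule but were left unnamed for their leading genes or low UMIs. Their share of cells was 19.8%, 16.5% and 41.6% at E17.5 (brachial, inguinal, mesenteric), 3.61%, 4.49% and 1.36% at P2, and 12.3%, 12.1% and 2.65% at P60. Mixed clusters are not counted in these shares and held 0.601%, 0.234% and 47.2% of the P60 cells. Adipocyte-lineage-like clusters are not counted either and held 31.5%, 50.4% and 0% of the E17.5 cells.

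The clustering was redone after results of an earlier run had been seen, because rounding in single precision and approximate neighbours in the doublet scores gave other P60 clusters on another processor type. It was changed to double precision and exact neighbours, and the outcome was kept as it came; 4 versions were seen in all. The earlier versions are not tabled here, so how far results moved between them is not shown; the adult blood endothelial-like share was seen to move in 1 version. In an earlier version some genes passed in the lymphatic endothelial-like class, where 0 pass here, and 3 planned tests of RNA from other cells in that class were dropped with them. A further clustering seed was added to the alternatives for this reason.

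UMI counts were summed per library over the fibroblastic mesenchymal-like cells (mural-like, adipocyte-lineage-like and mesothelial-like clusters excluded) and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM, glmQLFit and glmQLFTest. One additive model of node and age over the 9 libraries served all 5 mesenchymal-like comparisons, so the residual spread is the node-by-age remainder with 4 degrees of freedom. The comparisons were mesenteric against the mean of the 2 skin-draining nodes, inguinal against brachial, and each pair of ages. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Lymphatic and blood endothelial-like sums were tested for mesenteric against skin-draining nodes on the 6 libraries of P2 and P60, with 2 residual degrees of freedom, since an E17.5 library held fewer than 50 such cells. Standard errors are the log2 fold change divided by the root of the F statistic. With 1 library per group no test was made within an age; shares carry exact binomial (Clopper-Pearson) 95% intervals and counts exact Poisson intervals, which cover counting error only. Within an age, genes were named by size alone, at 4-fold or more and 50 UMIs or more in the higher library, with a library below 3 counts set to 3. Gene groups were 24 lists fixed before the files were opened, tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, where at least 3 members were measured, first with a preset correlation of 0.01 and again with the correlation estimated from the data. Counts of members that pass are also given with the adjustment made over the list alone. Shares of cells with a UMI of a gene were computed after thinning each cell to 1000 UMIs.

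Genes were named by a rule fixed before the files were opened. It takes the 10 largest changes each way among passing genes with the same sign in every block and a mean log2 CPM of at least 3, without predicted, ribosomal, mitochondrial and sex-linked genes. It adds up to 4 members of each gene group with the smallest adjusted p, whether or not they pass. It further adds all Hox genes, Tbx4, Tbx5, Pitx1, Isl1, Nkx2-3, Wt1, Ccl19, Ccl21a, Cxcl13, Madcam1, Tnfsf11, Vcam1, Icam1, Pdpn and Pecam1 in every library, and within each age the 5 largest differences each way under the size rule. Other genes are marked where they appear. Some results that the rule would name are not reported here.

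Alternatives covered the size factors, the test (DESeq2 1.42.0 and limma-voom), the low-count filter, the cell filters, the doublet calls, the resolution, equal cells and UMIs, the make-up of the class, each library or block left out, and the model without a block. Alternatives chosen after the data were seen took leading genes against other classes, added back the clusters kept out or the adipocyte-lineage-like clusters, left out genes with shared or overlapping sequence, changed the clustering seed, and dropped the P2 libraries from P60 against E17.5.

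The tests were tested on simulated data: negative binomial counts were drawn for the real genes from their mean levels, the real library sizes and the trended dispersion, with 200 genes changed, 50 at each of 4 known folds. Of these, 44.0% at 2-fold, 88.0% at 4-fold and 100% at 8-fold passed for mesenteric against skin-draining nodes, with 7 false calls among 13964 unchanged genes. The 4-fold share was 92.0% for inguinal against brachial, 90.0% for P2 against E17.5, 88.0% for P60 against P2, 94.0% for P60 against E17.5, 96.0% for lymphatic and 94.0% for blood endothelial-like sums. The simulated spread is the fitted node-by-age remainder, since the spread between animals of one node and age cannot be measured here. The changed genes were drawn only from those above a floor of mean counts, and each gene had the same mean level in every library before the change. The shares therefore do not hold for low-count genes or for genes whose own spread exceeds the trend.

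Left out were the barcodes and clusters above, the genes listed in only 1 kind of table, and any test of the classes present in too few libraries. Pseudotime, cell-to-cell signalling and regulator inference were not run, since the comparisons asked did not need them.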

Results

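Single-cell RNA counts were collected from 9 libraries of mouse lymph node cells depleted of blood cells: brachial, inguinal and mesenteric nodes at E17.5, P2 and P60, 1 pooled library each. After filtering, 5039, 4748 and 5286 cells remained at E17.5 (brachial, inguinal, mesenteric), 2464, 4367 and 2725 at P2, and 8991, 9415 and 5406 at P60. Median UMIs per cell were 6404, 6318 and 5447 at E17.5, 6339, 5237 and 6062 at P2, and 1893, 1978 and 1235 at P60, so adult cells were counted at lower depth. The mesenchymal-like sums that carry most comparisons hold 12895147, 9605226 and 16538022 UMIs at E17.5, 10645306, 13882986 and 11820610 at P2, and 4312998, 5188269 and 1795706 at P60. At the smallest of these, 1 UMI is 0.557 CPM. The ages also differ in sort, enzymes and, for P2, genotype and counting pipeline, so every age difference below is one of age and preparation together. The share of lymphoid-stroma-like cells within the mesenchymal-like class, given below, also differs between ages, so a change can be one of class make-up. In the 3 P60 libraries the Y-linked gene Ddx3y had 0 UMIs, against 27.2, 28.6 and 22.3 CPM at E17.5, so the sex of the pools differs between ages as well.

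Which cell classes does each library hold? Fibroblastic mesenchymal-like cells, which carry Pdgfra (uncertain, overlapping exons) and fibrillar collagen genes, made up 40.4% (95% interval 39.0% to 41.8%), 30.8% (29.5% to 32.2%) and 49.9% (48.5% to 51.2%) of cells at E17.5. They made up 66.8% (64.9% to 68.7%), 62.6% (61.2% to 64.0%) and 68.1% (66.3% to 69.8%) at P2, and 23.2% (22.3% to 24.1%), 24.8% (23.9% to 25.7%) and 19.7% (18.7% to 20.8%) at P60. Adipocyte-lineage-like cells, marked by Pparg and Fabp4, were 31.5% and 50.4% of the brachial and inguinal E17.5 cells and 4.42% and 2.22% at P2, with 0 such cells in either mesenteric library. At E17.5 they were clusters 0 and 2, each with 7 fibroblast markers detected, at mean log2 ratios of 1.31 and 1.03 against the bound of 1. The leading genes of cluster 0 (462 brachial and 631 inguinal cells) held 0 adipocyte-lineage markers, with Birc5, a mitotic gene, among them. Blood endothelial-like cells were 8.00%, 10.5% and 2.94% at P2 and 41.1%, 39.4% and 14.4% at P60, and lymphatic endothelial-like cells 4.79%, 4.47% and 2.72%, then 13.2%, 15.2% and 11.7%. The lymphatic shares at P60 leave out cluster 8 (536, 533 and 73 cells), which scored highest on the lymphatic list. It was left unnamed since its leading genes held 1 follicular dendritic marker and 0 endothelial ones. With another clustering seed the P60 blood endothelial-like shares were 25.7% in the brachial and 9.34% in the mesenteric library, and 2350 of 9415 cells in the inguinal one. Erythroid-like cells, named by their haemoglobin genes, were 7.52%, 2.04% and 0.0378% at E17.5, and the summed counts of their clusters also carried markers of other classes. Cluster 3, with 366 of the 379 brachial ones, carried 7 fibroblast and 6 lymphoid stroma markers, with Cxcl13 among its leading genes, and cluster 11 carried 5 endothelial markers. Mural-like cells, which wrap vessels, were 2.84%, 4.40% and 5.21% at P2 and 2.48%, 1.32% and 1.70% at P60, and follicular dendritic cell-like cells 0.245%, 0.297% and 0.629% at P60. The mural-like order of nodes at P2 rests on the naming rule, which left unnamed clusters 3 (108, 264 and 33 cells) and 19 (31, 131 and 7), with Rgs5 among their leading genes, and cluster 27 (65 mesenteric cells), led by Actg2 (both genes chosen after their values were seen).

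Within the mesenchymal-like class, lymphoid-stroma-like cells, which express chemokines and cytokines of the T and B cell areas, were 37.6%, 6.90% and 69.4% at E17.5, 79.8%, 82.3% and 15.6% at P2, and 99.7%, 95.5% and 97.4% at P60. These shares depend on the rule of at least 4 detected markers. Some P60 clusters of other classes reached it too, for example haematopoietic-like cluster 14 (5 markers) and blood endothelial-like cluster 6 (4). P60 clusters 4 and 20 scored highest on the fibroblastic list and cluster 9 on the neuronal one. E17.5 clusters 4, 15 and 18 and P2 clusters 0 and 12 scored highest on the lymphoid stroma list. Adventitial-like fibroblasts, which carry Cd34 and Pi16 (both uncertain, antisense overlap), were 50.9% and 74.5% of the class in the brachial and inguinal E17.5 libraries with 0 such cells in the mesenteric one, and 60.6% in the mesenteric P2 library. The mesenteric cells mostly fell in clusters of their own. At E17.5 cluster 1 held 45.2% and 63.9% of the brachial and inguinal class while clusters 15 and 13 held 45.5% and 30.6% of the mesenteric one. At P2 clusters 2 and 0 held 33.5% and 32.9% of the brachial class, cluster 0 46.4% of the inguinal one and cluster 23 60.5% of the mesenteric one. At P60 cluster 4 held 86.2% and 75.2% of the brachial and inguinal class and cluster 20 81.7% of the mesenteric one. Unnamed cells were 19.8%, 16.5% and 41.6% at E17.5, 9.25%, 13.5% and 5.21% at P2 and 18.8%, 18.0% and 51.2% at P60. Of the mesenteric P60 cells, 47.2% lay in clusters whose summed counts carry both fibroblast and endothelial markers, against 0.601% and 0.234% in the skin-draining nodes. These shares were not tested between libraries, and the intervals cover counting error only. The E17.5 shares moved with the clustering, for example to 62.1% and 55.9% mesenchymal-like cells in the brachial and inguinal libraries at a finer resolution, where adipocyte-lineage-like cells were 9.66% and 10.9% and erythroid-like cells 0.159% and 0.590%.

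**Figure D1:**
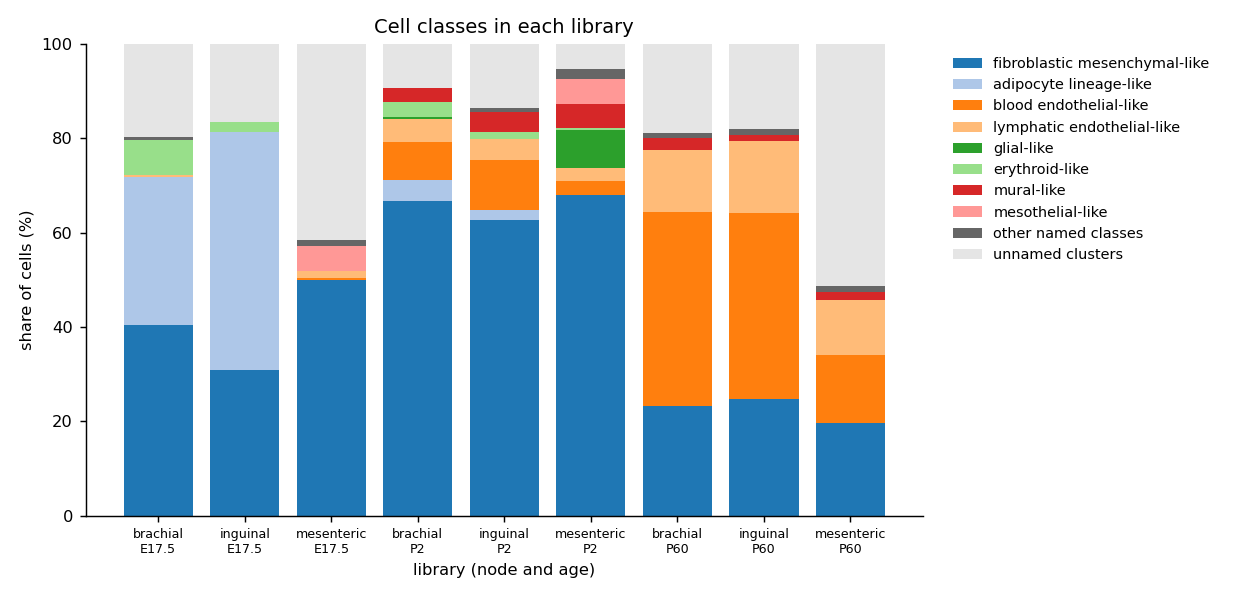
Cell classes per library. Each bar is 1 library (x axis, node and age), and the y axis is the share of its cells in percent, coloured by marker-based class. The mesenchymal-like class is largest at P2 and blood endothelial-like cells are most frequent in the skin-draining P60 libraries.

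Which mesenchymal-like genes differ between mesenteric and skin-draining nodes on average over the ages? Nkx2-3, a homeobox factor of gut and spleen mesenchyme, was higher in mesenteric cells by 10.43 ± 0.48 log2 (adjusted p = 0.00321, edgeR quasi-likelihood test, Benjamini-Hochberg), at 68.4, 86.2 and 104 CPM in the mesenteric libraries of E17.5, P2 and P60 and at most 5 UMIs in any skin-draining library. Wt1 and Isl1, factors of the visceral lining and of splanchnic mesoderm, were higher by 8.47 ± 0.49 and 7.92 ± 0.41. In the other direction, Tbx15 and En1, which pattern the body wall and limb, were lower, Tbx15 by -7.67 ± 0.38, as was Shox2, a limb skeletal factor, by -9.38 ± 0.56 (uncertain, antisense exon overlap). Tbx15 was read at 25.3, 22.4 and 0.181 CPM at E17.5, and 39.5, 30.9 and 0.0846 at P2 (brachial, inguinal, mesenteric), with 0 UMIs in mesenteric P60 cells, and En1 at 25.1, 24.6 and 0 and at 16.5, 25.2 and 0.0846 (adjusted p = 0.000848 for both in the same test). At P60 none of Wt1, Isl1, Tbx15, En1 and Shox2 was among the 5 largest mesenteric differences each way under the size rule.

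In all, 39 of 14164 tested genes passed, 28 higher and 11 lower in mesenteric cells (edgeR quasi-likelihood test, Benjamini-Hochberg, n = 9 libraries), and 1385 had an unadjusted p under 0.05. Of 13 limb and body wall factors, 7 fell, 0 rose and 6 did not pass (8 fell and 2 rose when adjusted over the list alone). Twist1, a mesenchymal bHLH factor (-5.16 ± 0.38), Tbx18 (-5.03 ± 0.63, uncertain, antisense overlap) and Prrx1, a limb mesenchyme homeobox factor (-1.14 ± 0.14), were among those that fell. Of 11 visceral factors, 4 rose, 0 fell and 7 did not pass (7 rose and 1 fell adjusted over the list alone); the fourth was Tcf21, a bHLH factor of visceral mesenchyme, at 8.30 ± 0.79. Both lists passed camera with the preset correlation (adjusted p = 1.18e-07 each), with an adjusted p = 0.249 each with an estimated correlation. The fitted log2 values of genes with 0 counts on one side depend on the prior count.

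Rspo3, a secreted Wnt amplifier, was higher by 1.99 ± 0.20 (uncertain, antisense overlap) and was the 1 of 12 Wnt pathway genes that passed, with 5 passing over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.249 with an estimated correlation). Among the largest changes were Fmo2, a flavin monooxygenase (3.13 ± 0.30), Clec11a, a bone growth factor (2.64 ± 0.36), Sparcl1, a matricellular protein (2.32 ± 0.26), the ephrin Efna5 (2.12 ± 0.25), Wfdc1 (2.01 ± 0.22) and the matrix protease Mmp16 (1.42 ± 0.15). Shank1 (2.29 ± 0.23), Hmcn1 (1.79 ± 0.20) and Runx1, a blood and stromal transcription factor (1.17 ± 0.16), also passed and are uncertain through antisense overlap. Hoxd8, a positional Hox gene, fell by 2.16 ± 0.26 and was the only member of its 8 measured Hox groups 6 to 8 that passed, with 2 higher and 2 lower over the list alone. Of the 13 Hox genes of groups 1 to 5 and the 8 of groups 9 to 13, 0 passed, with 1 lower, and 2 higher and 2 lower, over the list alone. Of the 17 lymphoid stroma factors 0 passed (edgeR quasi-likelihood test; camera adjusted p = 0.397, and adjusted p = 0.809 with an estimated correlation), with Lepr at -1.01 ± 0.33 and Ccl19, uncertain through shared 3' sequence, at -1.25 ± 0.62.

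With the preset correlation camera also called, among the lists given here, the NF-kB list (adjusted p = 0.0280), MHC class I (0.0160), MHC class II (0.0249), fibrillar and basement membrane matrix (0.0160) and adipogenic genes (0.0408) lower and smooth muscle genes (0.0160) higher. With an estimated correlation each of these had an adjusted p = 0.677, and in each list 0 members passed (edgeR quasi-likelihood test), with 1 matrix gene and 3 adipogenic genes lower and 2 smooth muscle genes higher over the list alone. Col6a3, a microfibril collagen, stood at -0.73 ± 0.16, H2-K1, a classical MHC class I chain, at -1.11 ± 0.50, Pparg, the adipocyte master regulator, at -5.62 ± 1.69, and the smooth muscle actin Actg2 at 3.19 ± 0.84. By DESeq2 342 genes passed and by limma-voom 107; with lymphoid-stroma-like cells alone the count was 189, without the P60 libraries 0, without the P2 libraries 14 and with no age block 5. Leaving out brachial E17.5 gave 8 genes, brachial P2 8, inguinal P2 12, brachial P60 13, inguinal P60 14, mesenteric P2 156 and mesenteric P60 61.

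**Figure D2:**
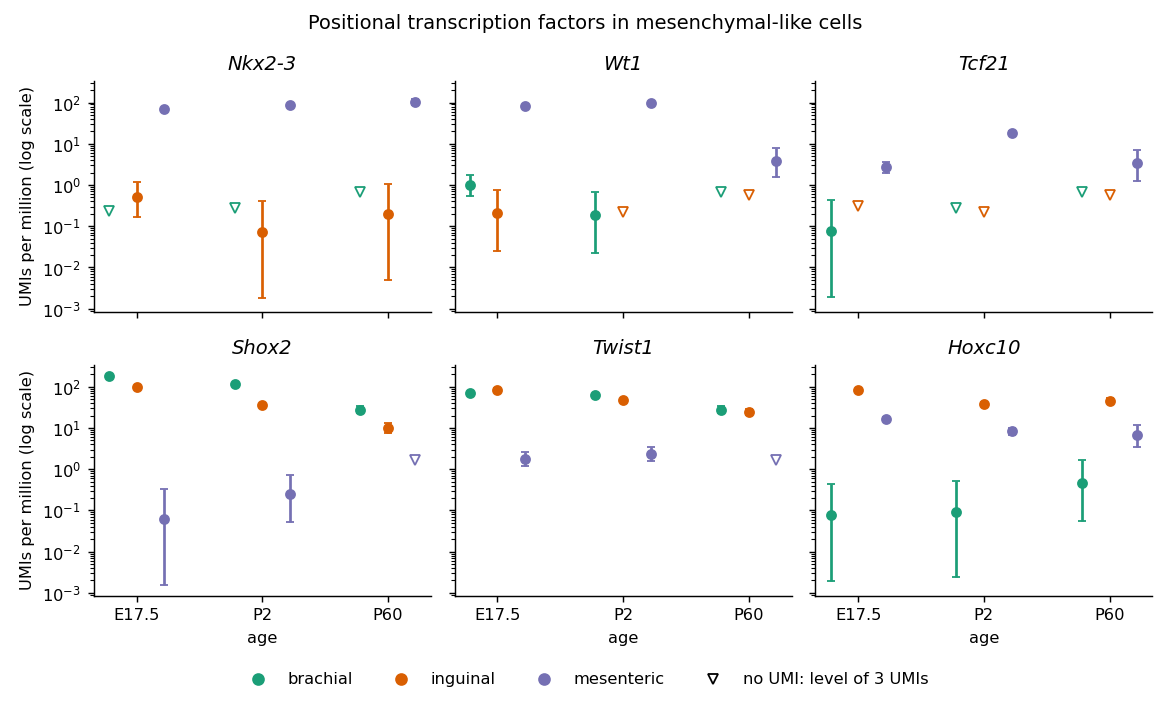
Counts scaled to the library total (CPM) of 6 positional genes in the mesenchymal-like sum of each library. Each point is 1 library, the x axis is age, the y axis is CPM on a log scale, colours are nodes and bars are 95% Poisson intervals of the count; open triangles mark libraries with 0 counts, drawn at the level of 3 UMIs. Nkx2-3, Wt1 and Tcf21 stand high in mesenteric libraries, Shox2 and Twist1 in skin-draining ones and Hoxc10 in inguinal ones. Shox2 and Hoxc10 are uncertain through exon overlap.

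Which genes differ between inguinal and brachial nodes? Hoxc10, a posterior Hox gene active in hind limb and trunk mesoderm, was higher in inguinal mesenchymal-like cells by 8.51 ± 0.48 log2 (adjusted p = 0.00379, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 9 libraries) and was the only 1 of 14164 genes that passed, with 165 at an unadjusted p under 0.05. It was read at 83.5, 39.0 and 46.1 CPM in inguinal cells of E17.5, P2 and P60, at 1, 1 and 2 UMIs in brachial cells, and at 16.7, 8.29 and 6.68 CPM in mesenteric cells. Its exons overlap another gene of the same strand by 166 bases, so its count is uncertain, and without such genes 0 passed. The neighbouring Hoxc9 stood at 2.83 ± 0.35 with an adjusted p = 0.480 in the same edgeR quasi-likelihood test with Benjamini-Hochberg, at 3.95, 9.21 and 12.1 CPM in brachial and 63.0, 49.4 and 55.3 in inguinal cells. Tbx5, a forelimb and heart factor, was read at 5.97, 3.23 and 0 CPM at E17.5 (brachial, inguinal, mesenteric), and Pitx1, a hind limb factor, at 0, 6.56 and 0.0605 CPM (uncertain, exon overlap). Tbx5 stood at -1.43 ± 0.50 and did not pass. Of the 24 gene groups 0 passed camera, with a smallest adjusted p = 0.0600 with the preset and 0.796 with the estimated correlation. DESeq2 gave 4 genes, limma-voom 1 and lymphoid-stroma-like cells alone 4. Without brachial P2, without inguinal P60, without all P2 or all P60 libraries, or with no age block, 0 passed.

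What differs between nodes within each age? At E17.5, 235 genes met the size rule for higher and 200 for lower in mesenteric cells, at P2 260 and 113, and at P60 24 and 32. Stmn2, a microtubule regulator best known from neurons, was 146-fold higher at E17.5 and 233-fold at P2 than in the higher skin-draining library. It is a neuronal marker of the naming rule, so its level in the class depends on that rule. Through it E17.5 cluster 14 (5, 11 and 2046 cells) and P60 cluster 3 (1028, 1049 and 76) were left unnamed, each with 7 fibroblast markers detected (brachial, inguinal, mesenteric). At E17.5 Agt, the angiotensin precursor, was 222-fold lower in mesenteric cells, and Car3, a carbonic anhydrase of fat and muscle, had 692 and 976 UMIs in brachial and inguinal cells and 0 in mesenteric ones, at least 296-fold. Both are among the leading genes of adipocyte-lineage-like clusters, a class with 31.5%, 50.4% and 0% of the E17.5 cells that enters no sum. At P2 Timd4, a phosphatidylserine receptor, was 81.8-fold lower, and Clps, a pancreatic colipase, was at least 237-fold higher, beside Ctrb1, a pancreatic protease precursor, at 328-fold. The same library alone held 27 epithelial-like cells (0.991%), with Ctrb1 and Clps among their leading genes. At P60 the mesenteric cells held more Cxcl14, a chemokine (26.9-fold), and Iyd, a deiodinase (27.2-fold), and less Cyp2f2, a cytochrome P450 (68.3-fold, uncertain, antisense overlap), and Sostdc1, a BMP and Wnt antagonist (14.2-fold). Twist1 had 0 mesenteric UMIs at P60, at least 14.8-fold lower. Between the skin-draining nodes, 16 genes met the rule for higher and 112 for lower in inguinal cells at E17.5, 15 and 15 at P2, and 24 and 3 at P60. Hbb-bt, a haemoglobin gene, was 33.0-fold lower in inguinal E17.5 cells (uncertain, shared 3' sequence), and it leads cluster 3, which held 366 brachial and 53 inguinal cells and enters no sum. Aldh1a2, a retinoic acid-producing enzyme, was lower in inguinal cells by 14.2-fold at E17.5 and 18.4-fold at P2. Pi16, an adventitial fibroblast marker, was 33.5-fold higher in inguinal P60 cells (uncertain, antisense overlap), where adventitial-like cells were 4.54% against 0.336% of the class. Each value compares single libraries, so no test was made.

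Which genes differ between P60 and E17.5, the 2 ages that share a counting pipeline? In adult mesenchymal-like cells Inmt, a methyltransferase, rose by 10.32 ± 0.51 log2, Lepr, the leptin receptor, by 7.07 ± 0.45 and Cxcl12, a homing chemokine, by 3.25 ± 0.25 (adjusted p = 0.000118, 0.000289 and 0.000530, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 9 libraries). Antigen presentation genes rose, with the class I chain H2-D1 from 97.7, 39.9 and 31.5 CPM to 2549, 3183 and 3131. Dlk1, an imprinted regulator of precursor cells, fell by 10.74 ± 0.83, from 6813, 10085 and 3620 CPM to 4.64, 3.08 and 4.46. Every measured cell cycle gene fell.

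Of 14164 genes 4634 passed, 2257 higher and 2377 lower at P60 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 18 cell cycle genes fell (camera adjusted p = 1.75e-10), with Birc5, a mitotic survival protein, at -7.94 ± 0.81, Pclaf, a replication clamp partner, at -7.66 ± 0.76 and the helicase Mcm6 at -2.66 ± 0.22. All 11 MHC class I genes rose (2.52e-06), with H2-K1 at 5.93 ± 0.66 and the peptide transporter Tap2 at 3.67 ± 0.33 (uncertain, antisense overlap), and all 6 MHC class II genes (0.000482), with H2-Aa at 6.32 ± 0.75. Of 18 interferon response genes 15 rose and 1 fell (16 and 1 over the list alone; 1.76e-05), among them the interferon regulator Irf7 (2.54 ± 0.34, uncertain, antisense overlap) and Ifi27 (1.07 ± 0.15). Of 11 complement genes 8 rose and 1 fell (1.76e-05), with the C1 inhibitor Serping1 at 3.58 ± 0.19 and C4b at 5.79 ± 0.47. Of 17 lymphoid stroma factors 9 rose and 0 fell (7.57e-05), among them Bst1, a stromal ectoenzyme (6.42 ± 0.77, uncertain, antisense overlap), and Ccl21a, a T cell zone chemokine (9.54 ± 0.98, uncertain, 73.3% of its 3' sequence shared). With an estimated correlation the adjusted p = 0.415 for cell cycle, both MHC lists, interferon and lymphoid stroma, and 0.351 for complement. Pecam1, an endothelial marker, was read higher in these sums at P60 than at E17.5, and RNA of other classes was not tested there. P60 cluster 10, with Birc5 among its leading genes, was named blood endothelial-like and enters no mesenchymal-like sum (41, 50 and 19 cells). Its summed counts carried 5 endothelial, 7 lymphoid stroma and 1 fibroblast marker.

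Other lists moved as well at P60. Of 14 inflammatory genes 9 rose and 0 fell (camera adjusted p = 0.000576, and adjusted p = 0.493 with an estimated correlation), with the acute phase gene Saa3 at 4.23 ± 0.29, the prostaglandin synthase Ptgs2 at 4.32 ± 0.33 and the neutrophil chemokine Cxcl2 at 2.93 ± 0.32. Of 11 NF-kB genes 5 rose (0.0197, and adjusted p = 0.549 with an estimated correlation), with Birc3, an inhibitor of cell death, at 2.53 ± 0.31. Genes that respond to cell dissociation rose beside them: 7 of 15 immediate early genes (0.0161, and adjusted p = 0.549), with the phosphatase Dusp1 at 1.90 ± 0.38 (uncertain, antisense overlap), and 5 of 9 heat shock genes (0.00461, and adjusted p = 0.351), with Hspa1b at 5.60 ± 0.41. Of 20 matrix genes 10 fell and 2 rose (12 and 3 over the list alone; 0.0202, and adjusted p = 0.549), with Col5a1, a fibril-regulating collagen, at -2.43 ± 0.46 and the basement membrane collagen Col4a1 at 0.92 ± 0.18 (both uncertain, antisense overlap). Of 15 BMP and TGF-beta genes 5 rose (0.0161, and adjusted p = 0.351), with the matrix protein Tgfbi at 5.12 ± 0.63 and the inhibitor Smad7 at 0.99 ± 0.21. Crabp1, a retinoic acid carrier, fell by 4.95 ± 0.33 while Cyp26b1, which degrades retinoic acid, rose by 4.24 ± 0.64, and Ptch1, a Hedgehog receptor and target, rose by 2.25 ± 0.21. The positional factors Wt1 (-4.73 ± 0.79), Isl1 (-3.13 ± 0.64) and Twist1 (-1.50 ± 0.35) fell.

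Further large changes at P60 were Mustn1, a musculoskeletal protein (7.14 ± 0.26), Clu, a secreted chaperone (6.73 ± 0.66), Ccl9, a chemokine (6.47 ± 0.72), and Serpina10, a clotting inhibitor (6.26 ± 0.78), all higher, and Nrk (-10.37 ± 1.35), Gap43, a growth cone protein (-8.35 ± 1.63), and Mfap4 (-7.91 ± 1.24, uncertain, antisense overlap), lower. H19 and Igf2, imprinted neighbours, fell by 10.58 ± 0.91 and 9.79 ± 0.92, and both are uncertain through overlapping exons. Glycam1, a product of high endothelial venules and so a marker of another class, rose by 7.77 ± 0.98, beside blood endothelial-like shares of 41.1%, 39.4% and 14.4%. Of 5 sex-linked genes the 4 Y-linked ones fell and Xist, uncertain through overlapping exons, rose (camera adjusted p = 0.000957, and adjusted p = 0.351 with an estimated correlation). Without the genes that share or overlap sequence 2869 passed, and without the brachial or inguinal libraries 468 and 2012. Leaving out brachial E17.5 gave 2566, brachial P60 2471 and inguinal P60 2389. Lymphoid-stroma-like cells were 766 of 2035, 101 of 1464 and 1831 of 2637 cells of the class at E17.5. At P60 they were 2077 of 2084, 2229 of 2335 and 1038 of 1066. With these cells only, 99 of 108 named genes kept direction and side of the threshold, 7 no longer passed and 2 reversed.

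**Figure D3:**
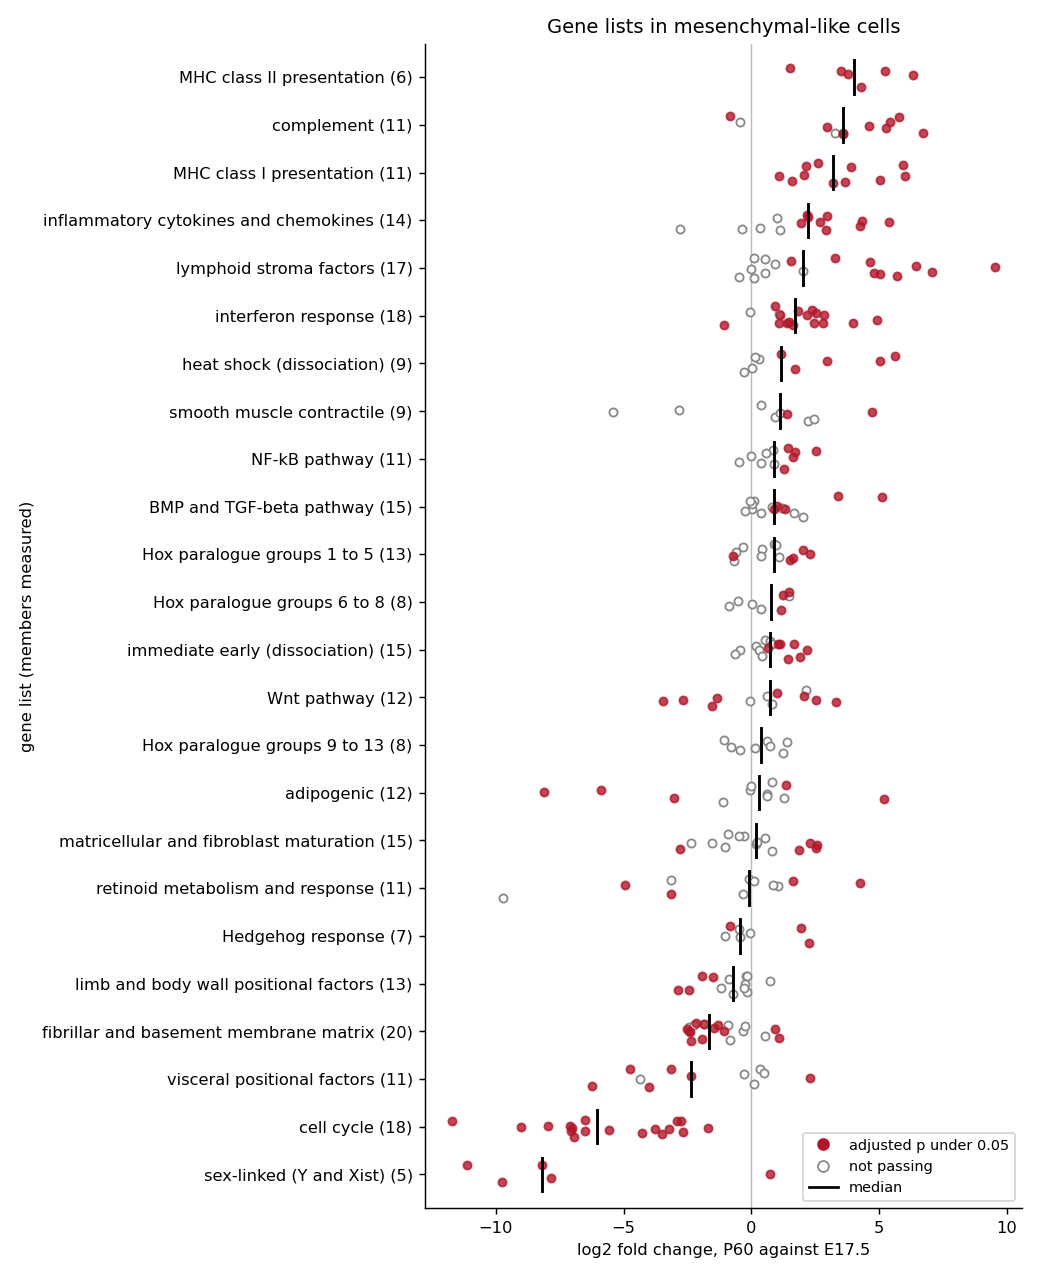
Gene lists in mesenchymal-like cells, P60 against E17.5. Each point is a gene, the x axis is its log2 fold change, the y axis is the list with the number of members measured; filled points passed the test, open points did not, and black bars are medians. Cell cycle genes lie to the left and antigen presentation, complement and stroma lists to the right.

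Which genes differ between P2 and E17.5? Il7, a T cell survival cytokine, rose by 4.22 ± 1.03 log2 (adjusted p = 0.0281, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 9 libraries; uncertain, antisense overlap), from 0.853, 0.521 and 14.3 CPM to 82.9, 82.8 and 61.3. Lepr rose by 3.20 ± 0.39 and Bst1 by 4.25 ± 0.71, while Icam1, an adhesion molecule also used in the E17.5 sort, fell by 2.54 ± 0.26 (Bst1 and Icam1 uncertain, antisense overlap). The inducible chaperones Hspa1b and Hspa1a rose by 6.16 ± 0.42 and 4.28 ± 0.33 (Hspa1a uncertain, antisense overlap). Of 14164 genes 2977 passed, 1459 higher and 1518 lower. Of 11 complement genes 7 rose and 1 fell (8 and 1 over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.921 with an estimated correlation). Of 14 inflammatory genes 5 rose and 1 fell (6 and 1; 0.0188, and adjusted p = 0.921), with Ptgs2 at 2.59 ± 0.31 and Cxcl2 at 2.54 ± 0.32, and of 9 heat shock genes 4 rose and 1 fell (6 and 1; 0.0188, and adjusted p = 0.887). Of 11 MHC class I genes 3 rose (5 over the list alone) and of 9 smooth muscle genes 4 (0.0431 each, and adjusted p = 0.921 each with an estimated correlation). Mural-like cells, which carry smooth muscle genes and enter no sum, numbered 0 in each E17.5 library and 70, 192 and 142 at P2. The naming rule left unnamed E17.5 cluster 21, with 50 mesenteric cells led by Actg2. Of 17 lymphoid stroma factors 3 rose and 3 fell (4 and 3 over the list alone), with Ccl21a among those that fell, of 15 BMP and TGF-beta genes 5 rose (6 over the list alone), with Smad7 at 2.01 ± 0.21, and of 18 cell cycle genes 0 passed. Ccl21a and the complement gene Cfb, which also fell, share or overlap sequence and were low only at P2 (0.385 and 0.0275 CPM), so their change is uncertain. Crabp1 fell by 3.73 ± 0.27 and Mgp, a calcification inhibitor, rose by 3.82 ± 0.57.

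In the naming rule, which leaves out mitochondrial genes, the largest drops at P2 were Tomm6 (-13.66 ± 0.47), Nme2 (-12.76 ± 0.43) and Ilk (-12.13 ± 0.40), followed by Rbm42, Aarsd1, Gng10, Tsix, Med10, Atp6v0c and Pgam1, down to -9.34 ± 0.33. All but Atp6v0c and Pgam1 overlap or share sequence with another gene and are uncertain, and all of them rose again by P60. Atp6v0c (299, 0.495 and 350 CPM at E17.5, P2 and P60) and Pgam1 (272, 0.495 and 73.0) were likewise low only at P2. Their change is therefore uncertain too, though no overlap was found. The mitochondrial genes mt-Co3 (-17.53 ± 0.50), mt-Atp6 (-15.70 ± 0.34) and mt-Co2 (-15.59 ± 0.48), chosen after their values were seen and uncertain through shared sequence, fell further, to 1, 3 and 1 UMIs over the 3 P2 sums. Among the largest gains, Vps25, Slc5a3 and Coro1b are uncertain for the same reason, Sept2 was not matched to the annotation, and Znrf3, a Wnt receptor ligase (4.09 ± 0.26), and Wdr89 (4.09 ± 0.22) had no overlap. The 3 P2 libraries were counted with other software. Without the genes that share or overlap sequence 1222 passed, with equal cells and UMIs 1712, and without the brachial, inguinal or mesenteric libraries 463, 1000 and 5537. Leaving out brachial E17.5 gave 1134, inguinal E17.5 1678, mesenteric E17.5 4487, brachial P2 1077 and inguinal P2 1744.

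Which genes differ between P60 and P2? Proliferation genes fell, with Mki67, a marker of cycling cells, from 84.5, 125 and 54.8 CPM to at most 3 UMIs per library (-7.32 ± 1.05, adjusted p = 0.00232, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 9 libraries), Birc5 by 7.24 ± 0.80 and Dlk1 by 8.60 ± 0.77. Lepr rose by 3.87 ± 0.38, Cxcl12 by 2.66 ± 0.25, H2-D1 by 3.96 ± 0.59 and Saa3 by 6.28 ± 0.33. Of 14164 genes 5366 passed, 2685 higher and 2681 lower at P60. All 18 cell cycle genes fell (camera adjusted p = 3.93e-09), with Mcm2 at -3.80 ± 0.31. Of 18 interferon genes 13 rose (15 over the list alone; 8.47e-05), of 11 MHC class I genes 10 (0.000272), of 6 MHC class II genes 6 (0.00483), of 11 complement genes 8 with 1 falling (0.00291) and of 17 lymphoid stroma factors 8 (0.00483). Cfb and Ccl21a, among those that rose, are uncertain, being low only at P2. Of 20 matrix genes 10 fell (11 over the list alone; 0.00483), with Col1a1 and Col3a1, the main fibrillar collagens, at -2.51 ± 0.60 and -2.25 ± 0.53 (Col3a1 uncertain, overlapping exons), and of 15 immediate early genes 8 rose (9 over the list alone; 0.00318), with Jun at 2.01 ± 0.28 (uncertain, antisense overlap). Of 5 sex-linked genes 4 fell and Xist rose (0.00483), but Xist overlaps other genes on both strands and was low only at P2 (52.8 CPM, against 1117 at E17.5 and 1674 at P60), so its change is uncertain. Each of these lists had an adjusted p = 0.613 with an estimated correlation. Pecam1, an endothelial marker, was read higher in these sums at P60 than at P2, and RNA of other classes was not tested at P60. Of 13 Hox genes of groups 1 to 5, 5 rose (6 over the list alone; 0.00483, and adjusted p = 0.613), but Hoxb2, Hoxa3 and Hoxb3 overlap other genes and were low only at P2, so their change is uncertain.

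Other large changes between these ages were Agtr2, an angiotensin receptor (-7.28 ± 1.00), Ube2c, a mitotic ubiquitin enzyme (-8.59 ± 1.12, uncertain, antisense overlap), Cdca3 (-8.49 ± 1.01) and Nrk (-7.56 ± 1.34). Ccl21a (16.13 ± 1.24), Cfb (13.22 ± 0.50), Pltp (10.67 ± 0.36), H19 (-9.09 ± 0.87) and the histone gene Hist1h2ae (-7.46 ± 0.96) are uncertain through overlapping or shared sequence, as are most of the genes named above as low at P2. Il7 (uncertain, antisense overlap) was at 83.9, 83.1 and 84.1 CPM at P60. Without the genes that share or overlap sequence 2930 passed, and without the brachial or inguinal libraries 982 and 2555. Leaving out brachial P2 gave 2665, brachial P60 2941 and inguinal P60 2879.

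How many mesenchymal-like cells carry a lymphoid stroma gene? After thinning to 1000 UMIs, a UMI of Cxcl13, the B cell chemokine, was found in 31.8%, 5.95% and 30.6% of cells at E17.5, 51.1%, 68.6% and 5.14% at P2, and 52.1%, 34.3% and 8.59% at P60 (brachial, inguinal, mesenteric). Unthinned shares were 43.4%, 9.22% and 52.0%, then 75.9%, 81.9% and 12.2%, then 60.8%, 45.0% and 10.7%. Endothelial-like cells, the background class, had Cxcl13 in 6.67%, 0% and 0%, then 8.80%, 3.48% and 0.578%, then 1.85%, 2.00% and 2.82% of thinned cells. Tnfsf11, the RANK ligand that organises lymphoid tissue, was found in 8.89%, 1.57% and 13.7% at E17.5, 17.4%, 17.3% and 4.21% at P2, and 5.00%, 3.50% and 14.4% at P60, against at most 1.06% of endothelial-like cells (unthinned 27.9%, 4.71% and 44.8%, then 47.2%, 49.5% and 12.3%, then 8.78%, 6.72% and 21.2%). Nkx2-3 was found in 6.38%, 7.16% and 10.5% of the mesenteric cells of the 3 ages (unthinned 31.3%, 38.2% and 15.7%) and in 0.935%, 4.62% and 3.07% of mesenteric endothelial-like cells. Ccl19, uncertain since 57.8% of its 3' sequence is shared, was found in 26.4%, 4.37% and 16.7%, then 6.74%, 8.92% and 1.37%, then 87.4%, 87.4% and 83.4% (unthinned 37.6%, 8.40% and 38.5%, then 24.6%, 27.7% and 5.01%, then 94.4%, 92.7% and 86.9%), against 6.67%, 0% and 5.61%, then 0.704%, 0% and 0%, then 9.15%, 11.1% and 13.4% of endothelial-like cells. Median UMIs were 6074, 6235 and 6044 at E17.5, 6124.5, 4762 and 5972 at P2 and 1873.5, 2038 and 1534 at P60 in the mesenchymal-like class, and 5414, 7615 and 4224.5, 6774, 7658 and 5597, and 1845, 1901 and 1570 in the endothelial-like one. Cells under 1000 UMIs were left out: 0, 1 and 2, then 29, 0 and 26, then 24, 21 and 100 mesenchymal-like, and 0, 0 and 1, then 34, 0 and 17, then 505, 546 and 205 endothelial-like. The brachial and inguinal E17.5 background rests on 15 and 4 cells. Lymphoid-stroma-like cells were 290 of 1855 mesenteric P2 cells of the class, against 1314 of 1646 brachial and 2250 of 2734 inguinal ones. Left out were 366 brachial cells of E17.5 cluster 3, with Cxcl13 among its leading genes, and 2554 mesenteric P60 cells (47.2%) in mixed clusters with lymphoid stroma markers detected. Among the other clusters left out were P60 cluster 3 (1028, 1049 and 76 cells, 6 lymphoid stroma markers) and P2 cluster 16 (51, 196 and 33 cells, 7 markers). Both met the fibroblastic rule but were left unnamed, so skin-draining cells are missing as well. Whether the Cxcl13 shares differ by node or by the cells that enter the class was not tested.

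**Figure D4:**
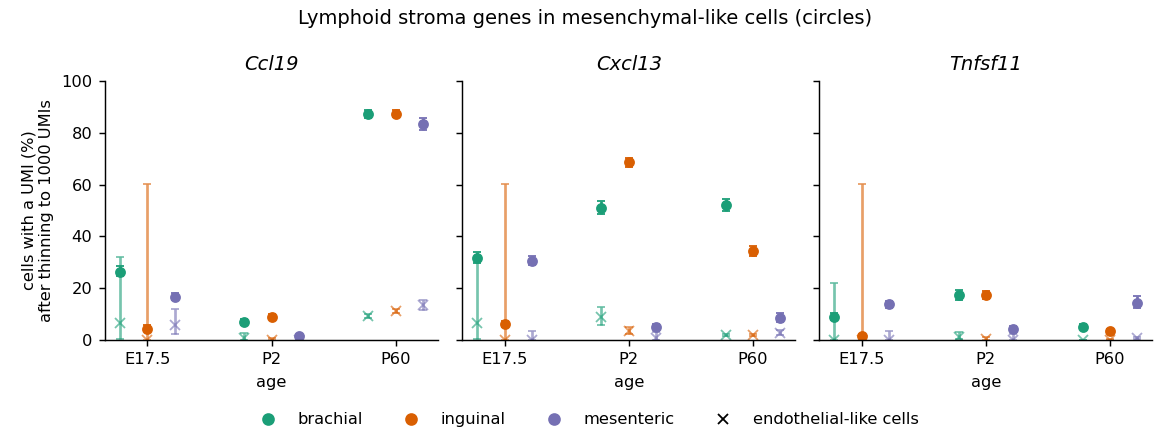
Share of cells with at least 1 UMI of Ccl19, Cxcl13 or Tnfsf11 after thinning each cell to 1000 UMIs. Each point is 1 library, the x axis is age, the y axis is percent of cells, colours are nodes, circles are mesenchymal-like and crosses endothelial-like cells, and bars are 95% binomial intervals. Cxcl13 is low in the mesenteric mesenchymal-like cells after birth, where the cells that enter the class differ between nodes. Ccl19 is uncertain through shared sequence.

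Do endothelial-like cells differ between nodes? In blood endothelial-like cells Nkx2-3 was higher in mesenteric nodes by 10.23 ± 0.43 log2 (adjusted p = 5.66e-07, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 6 libraries), with 46 and 106 UMIs in the mesenteric P2 and P60 libraries and at most 1 elsewhere. Scgb3a1, a secretoglobin, was higher by 4.23 ± 0.27, Rassf9 by 2.62 ± 0.24, Meis2, a homeobox cofactor, by 1.94 ± 0.28 and Tnfsf15, an endothelial cytokine, by 1.45 ± 0.23. Slc14a1, a urea transporter, was lower by -3.24 ± 0.43, Hoxd9 by -1.70 ± 0.28, Pf4, a platelet chemokine, by -1.56 ± 0.27 and Itih5 by -1.39 ± 0.21. Madcam1, the gut-homing addressin, was read at 550, 931 and 1261 CPM at P2 and 14.6, 8.04 and 1791 at P60 (brachial, inguinal, mesenteric), and at 5.21 ± 1.24 it did not pass. In all 27 of 11567 genes passed, 22 higher and 5 lower. The make-up of the class differed between nodes. Cluster 6 at P60, led by Glycam1, held 467 of 3696 brachial, 634 of 3713 inguinal and 174 of 777 mesenteric cells. Cluster 13 at P2, also led by Glycam1, held 91 of 197, 218 of 459 and 28 of 80. Whether the genes follow this mix was not tested. Of 9 heat shock genes 2 rose (4 over the list alone), with Hspa1b at 1.81 ± 0.16 (camera adjusted p = 0.000163). Of 14 matricellular genes 1 rose, Lum, a small matrix proteoglycan (2.91 ± 0.43; 3 over the list alone; 0.000163), and of 5 visceral factors 1 (0.00144). Camera also called interferon (7.04e-05), MHC class I (0.00366) and MHC class II (0.0289) lower and matrix (0.00307), immediate early (0.0411) and smooth muscle genes (0.0411) higher, with 0 members passing (4 interferon genes lower, 2 matrix genes and 1 smooth muscle gene higher over the list alone). Each of these 9 lists had an adjusted p = 0.773 with an estimated correlation. Markers of mesenchymal-like cells imply that their RNA makes up 3.08% and 2.15% of the mesenteric P2 and P60 sums, enough for 94.2% and 85.9% of the Lum counts, 55.2% and 40.3% of Plac8 (2.01 ± 0.33), 24.9% and 75.9% of Rarres2 (1.88 ± 0.32, uncertain, antisense overlap) and 3.96% and 3.54% of Nkx2-3. At P60 the same level covers 99.0% of the counts of Inmt. Leaving out brachial P2 gave 61 genes, inguinal P2 62, mesenteric P2 167, inguinal P60 60 and mesenteric P60 275.

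In lymphatic endothelial-like cells 0 of 10327 genes passed the same edgeR quasi-likelihood test with Benjamini-Hochberg (n = 6 libraries), and 595 had an unadjusted p under 0.05; DESeq2 and limma-voom were not run on this class. Gpc3, a cell-surface proteoglycan, stood at 4.17 log2, Gpx3, a secreted peroxidase, at 3.23 and Cd38, an NAD-consuming ectoenzyme, at 1.81, each with the smallest adjusted p = 0.0514. Cd38 was read at 15.9, 19.0 and 49.0 CPM at P2 and 48.9, 43.2 and 174 at P60 (brachial, inguinal, mesenteric), and Gpc3 at 1.76, 3.32 and 41.7 at P2. These 3 genes were chosen after their values were seen. Gpc3 is also among the leading genes of the mesenchymal-like clusters 23 at P2 and 20 at P60, which held 1122 and 871 mesenteric cells, and RNA of other cells was not tested in this class. The make-up of the class differed between nodes too. At P60 cluster 5 held 558 of 1190 brachial, 647 of 1428 inguinal and 483 of 633 mesenteric lymphatic endothelial-like cells. Unnamed P60 cluster 8, with 536, 533 and 73 cells, scored highest on the lymphatic list but did not enter the tested sums. Of 14 matricellular genes 0 passed (4 higher over the list alone), with camera adjusted p = 4.62e-08, and of 9 heat shock genes 0 (2 over the list alone; 0.0154). Camera called the Wnt and Hox 6 to 8 lists higher (0.0154 each) and cell cycle lower (0.00201), and each of the 5 lists had an adjusted p = 0.567 with an estimated correlation. Leaving out brachial P2 gave 15 genes, inguinal P2 54, mesenteric P2 256, brachial P60 13, inguinal P60 86 and mesenteric P60 367, and without a low-count filter 126 passed.

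Positions on GRCm38, all protein-coding genes of GENCODE vM21, are chromosome 19, 43612325 to 43615892 for Nkx2-3; chromosome 2, 105126529 to 105173616 for Wt1; and chromosome 13, 116298281 to 116309689 for Isl1. Tbx15 lies on chromosome 3, 99240381 to 99354259, En1 on chromosome 1, 120602418 to 120607992, and Hoxc10 on chromosome 15, 102966796 to 102971893. Lepr lies on chromosome 4, 101717404 to 101815352, Dlk1 on chromosome 12, 109452823 to 109463336, H2-D1 on chromosome 17, 35262730 to 35267499, and Cxcl13 on chromosome 5, 95956951 to 95961068.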

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

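All tests by splits of the libraries, the overlap test of the genes low at P2, the test in lymphoid-stroma-like cells alone and the Lum test were chosen only after the result was seen; the others were written before.

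Of the tested genes matched to the annotation, 136 stood at least 16-fold lower at P2 than at both other ages in mesenchymal-like cells. Of these, 121 (89.0%, 95% interval 82.5% to 93.7%) overlap another gene's exons or share 3' sequence, against 37.7% (36.9% to 38.5%) of the 14002 other matched genes, which is in line with reads on such sequence being counted differently in the P2 pipeline. A change confined to mesenchymal-like cells is argued against, since 83 of the 86 of these genes that could be measured there (96.5%) were also at least 16-fold lower at P2 than at P60 in lymphatic endothelial-like cells. Whether any of these genes also changed in the tissue stays open.

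The 39 genes that separate mesenteric from skin-draining mesenchymal-like cells could reflect another mix of named sub-groups, RNA of mesothelial-like cells or chance. Of the 39, 32 (82.1%) passed in the same direction in lymphoid-stroma-like cells alone. This cannot decide on the mix, since these cells are part of the sums that gave the 39 genes. At P60 they were nearly the whole class (2077 of 2084 brachial, 2229 of 2335 inguinal and 1038 of 1066 mesenteric cells). These cells also fell in different clusters, at P60 mostly cluster 4 in the skin-draining libraries and cluster 20 in the mesenteric one. Sub-groups within the lymphoid-stroma-like cells were not tested. RNA of mesothelial-like cells would give a median of 0.208% of the mesenteric counts of the 28 higher genes at E17.5 and P2, which argues against that source at these ages. The P2 source, cluster 25, also had Ins2 and Ins1, pancreatic hormone genes, among its leading genes. At P60 no cluster was named mesothelial-like and this was not tested. Among 27 splits of the nodes within ages, in a model with no term between the skin-draining nodes, the real one gave 92 genes and the highest other 3, so 1 split reached the real count. Every other split sets at least 1 mesenteric library among the skin-draining ones, so a real node difference raises its spread. The test was chosen after the result, and its model is not the one that gave the 39 genes. With 1 of 27 the smallest share possible, chance cannot be excluded. With 1 pool per node and age, a difference between the dissected tissues that is not one of the node stays open.

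The 22 genes higher in mesenteric blood endothelial-like cells could carry RNA of mesenchymal-like cells. That RNA would give a median of 2.48% of their counts over both mesenteric libraries, which argues against it for the set. For Lum it would give at least 85.9% of the counts in both libraries, which is in line with such RNA for this gene. The node difference itself was not tested further in this class.

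For inguinal against brachial nodes 4 splits exist, real 1 and highest other 0, with 1 split at the real count, which is too few for a share under 0.05. For P2 against E17.5 (real 2977, highest other 0), P60 against P2 (5366 and 0) and P60 against E17.5 (4634 and 0) 4 splits exist each, with 1 split at the real count, too few for a share under 0.05.

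A difference between groups marked 9 genes (Lyz2, Adgrd1, Cela1, Cpz, Dpt, Fbln5, Pi16, Lsamp and Rbp4) that were higher in the mesenteric library at 1 age and lower at another; the difference was not tested. Pi16 was 4.82-fold higher in mesenteric cells at P2 and 8.32-fold lower at E17.5, not tested and uncertain through antisense overlap. Adventitial-like cells were 50.9%, 74.5% and 0% of the class at E17.5 and 12.0%, 9.36% and 60.6% at P2 (brachial, inguinal, mesenteric). Signal in classes that enter no comparison was seen in the mesenteric libraries: glial-like cells were 8.11% of the P2 cells, mesothelial-like cells 5.11% at E17.5 and 5.14% at P2, and epithelial-like cells 0.991% at P2. The P2 mesothelial-like cluster 25 (140 cells) had the pancreatic hormone genes Ins2, Sst, Iapp and Ins1 among its leading genes, beside the mesothelial markers Upk3b, Msln and Krt19.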

How the results depend on the processing

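The alternatives were followed for named genes that passed and for 3 lymphatic endothelial-like genes that did not. Other named genes that did not pass were not followed. Of 9358 such values, 8332 kept direction and side of the threshold, 997 kept direction but no longer passed, 27 newly passed and 2 reversed. All 27 were of the 3 lymphatic genes, the only followed ones that could newly pass. Reversed were Smoc2 (0.77 log2) and Hoxb2 (0.37, uncertain, antisense overlap), for P60 against E17.5 in lymphoid-stroma-like cells only. The cause was not tested for any value here unless fewer genes or libraries give it. Genes passing for mesenteric against skin-draining nodes (39) became 342 by DESeq2, 107 by limma-voom, 105 with no low-count filter, 96 at 1000 detected genes, 189 in lymphoid-stroma-like cells only, 88 with the kept-out clusters, 65, 14 and 0 without E17.5, P2 or P60, and 5 with no block; inguinal against brachial (1) became 4 by DESeq2, 4 in lymphoid-stroma-like cells and 0 without shared-sequence genes, without P2, without P60 or with no block. P2 against E17.5 (2977) became 1712 at equal cells and UMIs, 1222 without shared-sequence genes, and 463, 1000 and 5537 without brachial, inguinal or mesenteric libraries; P60 against P2 (5366) became 2930, and 982 and 2555 without brachial or inguinal; P60 against E17.5 (4634) became 2869, and 468 and 2012, and 4846 without P2. Lymphatic endothelial-like genes (0) became 126 with no low-count filter, 6 with DESeq2 size factors, 5 with doublets kept and 6 with another seed; blood endothelial-like genes (27) became 148 with no low-count filter. Leaving out 1 library gave 8 to 156, 0 to 1, 1077 to 4487, 2665 to 6470, 2389 to 5732, 13 to 367 and 37 to 275 genes in this order, the lone pools being assumed to vary like the rest. With an estimated correlation 0 lists passed camera instead of 10, 5, 10 and 13 (mesenteric against skin-draining, P2 against E17.5, P60 against P2, P60 against E17.5), 5 (lymphatic) and 9 (blood). Mesenchymal-like shares moved at 1000 detected genes to 42.3%, 29.4% and 52.3% (E17.5), 61.4% and 46.3% (brachial and inguinal P2) and 16.8%, 20.2% and 9.95% (P60); at 5% mitochondrial UMIs to 64.6% and 46.1% (brachial and inguinal E17.5) and 70.4% (mesenteric P2); with doublets kept to 50.2%, 35.1% and 48.2%, 57.5%, 44.9% and 65.7%, and 22.0% and 23.3% (brachial and inguinal P60); at resolution 1.5 to 62.1%, 55.9% and 59.0% (E17.5); and with another seed to 53.2% and 44.8% (brachial and inguinal E17.5). With another seed the P60 blood endothelial-like shares were 25.7% (brachial) and 9.34% (mesenteric), and at 1000 detected genes the mesenteric one 35.2%. All 36 unthinned stroma shares moved. DESeq2 size factors turned no direction. No paired analysis was possible because animals are not labelled and each group holds only replicate number 1. Age still serves as a block between nodes in the model above. Adult depth limits the reading of rare genes: 1 UMI is 0.557 CPM in mesenteric P60, and a count of 0 there bounds a gene at 2.05 CPM. DESeq2 and limma-voom were not run on the endothelial-like classes.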

Other observations

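The genes of the sort markers differed between libraries of mesenchymal-like cells, with no test beyond the comparisons above. Vcam1, an adhesion molecule of stroma (uncertain, antisense overlap), was read at 276, 229 and 205 CPM at E17.5 (brachial, inguinal, mesenteric), 704, 1076 and 248 at P2 and 595, 634 and 716 at P60. Icam1 (uncertain, antisense overlap) was read at 267, 293 and 312, then 71.4, 80.1 and 42.7, then 525, 472 and 285 CPM. Pdpn, which encodes GP38, stood at 112, 93.6 and 100.0, then 125, 125 and 86.1, then 62.8, 70.2 and 78.5, and Pecam1, which encodes CD31, at 0.698, 0.937 and 0.726, then 7.61, 4.11 and 4.15, then 33.2, 27.0 and 35.1. Madcam1, carried by lymphoid organiser and marginal reticular cells, was read at 25.4, 9.68 and 72.3, then 104, 199 and 32.0, then 28.3, 38.4 and 134.

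Large unnamed clusters hold cells that enter no comparison. At E17.5 cluster 14 held 2046 mesenteric, 5 brachial and 11 inguinal cells, led by Stmn2, Atp1b1 (uncertain, antisense overlap), Mgp, Slit2 and Sparcl1, with Wt1 among its leading genes. At P60 cluster 21 held 2084 mesenteric cells, led by Pam (uncertain, overlapping exons), Abhd2 and Slc39a1, at a median of 1061 UMIs. At P60 cluster 3, led by Sfrp2 (uncertain, antisense overlap), Tnfsf13b, the gene of the B cell survival factor BAFF, and Sostdc1, held 1028, 1049 and 76 cells (brachial, inguinal, mesenteric), and cluster 8, led by Bmp2, Ccl20 and Coch, held 536, 533 and 73. These genes were chosen after their values were seen.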
